A study of Mus musculus with 3 samples.

How the data were processed

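Primary bone-marrow macrophages of C57BL/6 mice were stimulated with lipopolysaccharide (LPS) at 100 ng/ml and profiled by CUT&RUN, in which an antibody brings a nuclease to its target on the chromatin of permeabilised cells and the released DNA fragments are sequenced. The labels' treatment protocol gives 5 h of LPS and the series' design text gives 6 h, and the difference was left open. The series has 3 libraries of 500000 cells each, 1 with an antibody against the transcription factor ATF5, 1 against the histone mark H3K27ac and 1 against DRP1, which the series' design text names as the control. The label of the DRP1 antibody names a serine site of that protein. No antibody has a replicate library.

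The deposited peak list gives a chromosome, a start and an end for each peak. The labels of the ATF5 and the DRP1 sample both name it, as ATF5 against a control, with a further term, hist, that is not explained. It was read as the ATF5 library against the DRP1 library, from these labels and the series' design text, which names DRP1 as the control. The list itself does not state this, and the meaning of each peak and of the frequent length of 500 bp depends on it and on the unknown caller. Per the submitters' processing notes, Trim Galore, Bowtie2 and deepTools were used with the mouse build mm10. Their versions, the peak caller and its thresholds are not given in the sources used here. The list holds no score, p-value, fold or read count, so the read depth of the libraries and the height of each peak are unknown, and a region without a peak is a region below thresholds that are not known. The H3K27ac library was not analysed here. If the list compares ATF5 with DRP1 in this way, a site where DRP1 and ATF5 antibodies released DNA alike may be missing from it.

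Peaks were set beside the RefSeq gene table of GRCm38.p6, the assembly that mm10 names, which gives gene spans without strand, exons or sequence. The table holds 49997 genes. For 348 of them, 113 protein-coding, the listed position counts along an unplaced scaffold or a patch, as recognised from the table's order of starts, and these were left out, a step added after results had been seen, which left 21774 protein-coding genes on the numbered, X and Y chromosomes. The coordinates of peaks and genes were checked against each other by shifting all peaks: 14.2% of peak centres lay within 1000 bp of a gene boundary as listed, and 5.04% to 5.23% after shifts of 5000 or 10000 bp to either side.

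The plan made before the data were examined used transcription start sites, exon classes, promoter GC content, sequence motifs and peak scores. Without strand, exons, sequence or scores, either boundary of a gene (its lower or higher coordinate) took the place of the start site, so a boundary peak can lie at the start or at the end of a gene. Each peak centre was placed in the class boundary (within 1000 bp of a protein-coding gene's boundary), body (elsewhere inside a protein-coding gene) or other. Shares of peaks carry Wilson 95% intervals, and were set beside 1000 random placements of the same peak lengths along the annotated extent of the same chromosomes, from the first gene's start to the last gene's end. Peaks per Mb used the same extents and carry exact Poisson 95% intervals. A gene was counted as having a boundary peak when any part of a peak lay within 1000 bp of either boundary.

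For gene groups, 17 lists with 467 entries were fixed before the data were examined, and 465 entries matched the table, 12 of them through an older name. The unmatched ones, Mx1 and Mx2 of the interferon list, are not protein-coding in the table. A gene can be on several lists. Each list's share carries an exact binomial 95% interval, and its count was compared with 10000 random lists of the same size matched on gene length and on the number of genes within 100000 bp, each in quintiles. A list was called when at most 250 of the 10000 random lists held as many genes with a peak or more, a threshold at which 0.261 of 17 lists would be called by chance, given the steps a whole count can take. On the lower side 0 of the 17 lists could have been called with boundary peaks. With 1 library per antibody no p-value across samples can be given: these counts describe this peak list, peaks and genes are not replicates, and all intervals cover counting error only. No difference between lists was tested.

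The genes named are the 15 with the longest boundary peak, up to 12 members of the mitochondrial and integrated stress response lists, up to 4 members of each other list, in each case the longest peaks first, and Atf5, Dnm1l, Hspd1, Hspe1, Lonp1, Clpp, Atf4, Ddit3, Spi1, Tnf, Il1b and Alb whatever their value. Other genes named were chosen after their values were seen. The gene behind the lymphocyte list's boundary count is not reported here. Alternatives were the peaks longer than 500 bp (in place of the longer part by length, since the median length is itself 500 bp), windows of 500 and 2500 bp, all annotated genes, any overlap of 1 bp in place of the peak centre, peaks within 1000 bp merged, a peak anywhere in the gene or within 10000 bp of it, and unmatched random lists. Leaving out chromosomes X and Y, counting each peak once per list and the X ratio for longer peaks were added after seeing the data.

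The recovery of genes was tested on simulated peaks: all 200 genes given a planted boundary peak were recovered, and 436 of 436 genes checked by a direct search gave the same answer. In a separate check of the calling rule, 10 of 400 lists of random genes (2.5%) were called. At that rate 0.425 of the 17 lists would be called by chance, more than the 0.261 computed from the steps of a whole count. The reason for this difference was not tested. Lists of 30 genes were also built from the real peak list to hold a set number of members with a peak. They were called in 0% of draws when 3 members had a peak, 1% when 5 had one and 100% when 7 had one. These values show where the threshold falls, not how often a list with a true excess would be called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.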

Results

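ATF5, a bZIP transcription factor linked to the mitochondrial unfolded protein response, was mapped by CUT&RUN in mouse bone-marrow macrophages stimulated with LPS, the cell-wall component of Gram-negative bacteria that activates Toll-like receptor signalling. The series concerns mitochondrial fission in the defence of cells against bacteria. The comparison it implies is the ATF5 library against the library made with an antibody to DRP1, the GTPase of mitochondrial fission, which the series' design text names as the control, with 1 library of each. The labels of both of these samples name the peak list, as ATF5 against a control, and it is read as that comparison. There was no replicate, and the peak list gave positions only, so the read depth is unknown and no value below has a replicate error.

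The ATF5 list held 7583 peaks, which covered 4.46 Mb of the mouse genome (mm10). Peak length had a median of 500 bp and a mean of 588 ± 189 bp (SD over peaks) and reached from 309 to 3373 bp. Of the peaks, 5215 (68.8%) were exactly 500 bp long, 2365 (31.2%) were longer and 3 were shorter, while 269 exceeded 1000 bp. No peaks overlapped, and the smallest gap between neighbours was 501 bp. The longest peak lay on chromosome Y (90799020 to 90802392, 3373 bp), followed by peaks on chromosome 7 (75699568 to 75702270, 2703 bp), chromosome 13 at Klf6 (5870009 to 5872657, 2649 bp), chromosome 11 at Vmp1 (86581374 to 86583925, 2552 bp) and chromosome 5 near Cd36 (17842286 to 17844803, 2518 bp).

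Peaks were found on every chromosome, at 3.12 per Mb over the autosomes, with the lowest density on chromosome 4 (2.62 per Mb) and the highest on chromosome 19 (4.48 per Mb) and chromosome 11 (4.09 per Mb). Chromosome X held 72 peaks, or 0.430 per Mb (exact 95% interval 0.336 to 0.541), which was 0.138 times the autosomal density (95% interval 0.109 to 0.174). Among the peaks longer than 500 bp this ratio was 0.0917 (0.0552 to 0.152). Chromosome Y held 6 peaks, of which 5 lay between 90797196 and 90813970. Whether this stretch shares sequence with another chromosome was not examined, so these peaks are not shown to be particular to Y. The sex of the animals is not given in the labels.

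**Figure D1:**
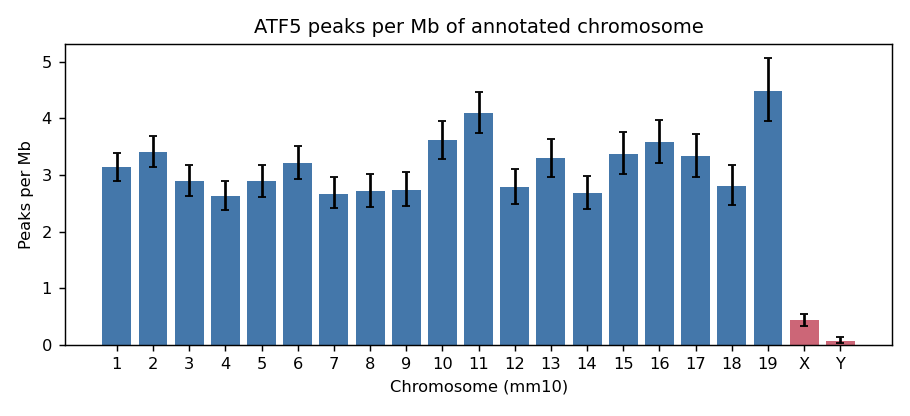
Bars show ATF5 peaks per Mb (y axis) for each mouse chromosome (x axis, mm10), and error bars show exact Poisson 95% intervals, which cover counting error only. The autosomes lie between 2.62 and 4.48 peaks per Mb, chromosome X at 0.430 and chromosome Y at 0.0662.

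ATF5 peaks were concentrated at the boundaries of protein-coding genes. Of 7577 peaks on chromosomes, 1079 (14.2%, Wilson 95% interval 13.47 to 15.05) had their centre within 1000 bp of a gene boundary, against a mean of 3.11% and a maximum of 3.87% over 1000 random placements, a 4.58-fold difference. Gene bodies held 3196 peaks (42.2%, 41.1 to 43.3), against 39.3% at random with a maximum of 41.3%. This difference did not hold throughout: the share in gene bodies lay within the random range for peaks longer than 500 bp (41.7%, maximum 43.0%), with a window of 2500 bp (37.8%, maximum 38.9%) and with all annotated genes (47.1%, maximum 47.7%). The remaining 3302 peaks (43.6%, 42.5 to 44.7) lay outside protein-coding genes and away from their boundaries, against 57.6% at random. With all annotated genes this class held 2608 peaks (34.4%). The density of peak centres was highest in the 250 bp just outside a gene, at 13.1 times the genome mean, and was 7.32 times the mean in the first 250 bp inside it. Peaks between 1 and 10 kb from a boundary made up 24.9% of the list against 18.6% at random, and peaks more than 100 kb away made up 20.6% against 35.4%. The size of the difference followed the window: it was 6.62-fold within 500 bp and 2.99-fold within 2500 bp, and 2.90-fold when the boundaries of all annotated genes were used. The gene table gives no strand, so starts and ends of genes were not separated.

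**Figure D2:**
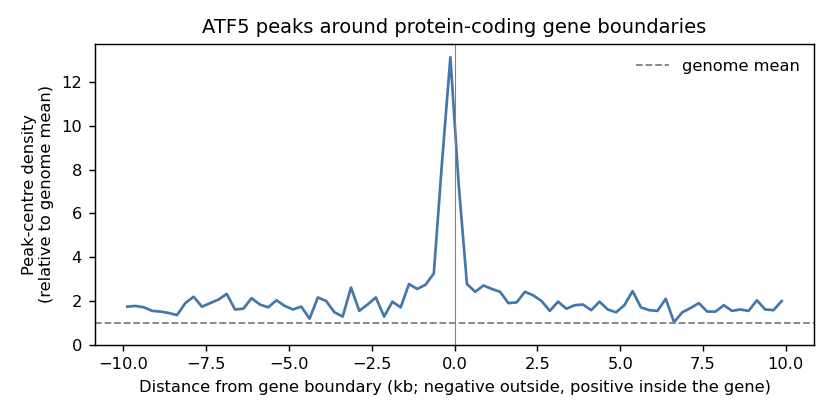
The line shows the density of ATF5 peak centres relative to the genome mean (y axis) by distance from a protein-coding gene boundary (x axis, kb, negative outside and positive inside the gene), in steps of 250 bp with both ends of each gene counted. It peaks at 13.1 in the step just outside the boundary, and the dashed line marks the genome mean.

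A boundary peak was found at 1441 of 21774 protein-coding genes (6.62%, 6.30 to 6.96), through 1209 distinct peaks. The longest lay at Klf6, a zinc-finger transcription factor gene, where 2 peaks touched the boundary windows, and at Vmp1, whose product takes part in autophagosome formation. Next came the chemokine gene Ccl4 with a peak of 2460 bp (chromosome 11, 83662878 to 83665337, centre 576 bp from the gene's higher end). A peak of 1982 bp lay at the junction of Dcakd and the N-myristoyltransferase gene Nmt1, whose spans overlap there, and counted for both. Atp6v1e1, a subunit gene of the lysosomal proton pump, had a peak of 1889 bp, and Rchy1, a ubiquitin ligase gene, had one of 1805 bp. Pxn, the gene of the adhesion protein paxillin, shared a peak of 1886 bp with the mitochondrial sirtuin gene Sirt4. Cux1 and the adaptor gene Sh2b2 shared a peak of 1804 bp. Cd14, the gene of the co-receptor for LPS, had a peak of 1759 bp (chromosome 18, 36726452 to 36728210) and Acod1, whose enzyme makes itaconate in activated macrophages, a peak of 1724 bp (chromosome 14, 103057536 to 103059259) that began 962 bp beyond the gene. Dennd1b had a peak of 1671 bp. Ddit3, which encodes the stress-induced transcription factor CHOP, had one of 1559 bp (chromosome 10, 127289336 to 127290894), shared with its neighbour Mbd6. Peak length was not taken as a measure of signal height, which the list does not give. Longer peaks tended to stand earlier in the list (Spearman correlation of row number with length -0.728). What sets the order of the rows is not stated.

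**Figure D3:**
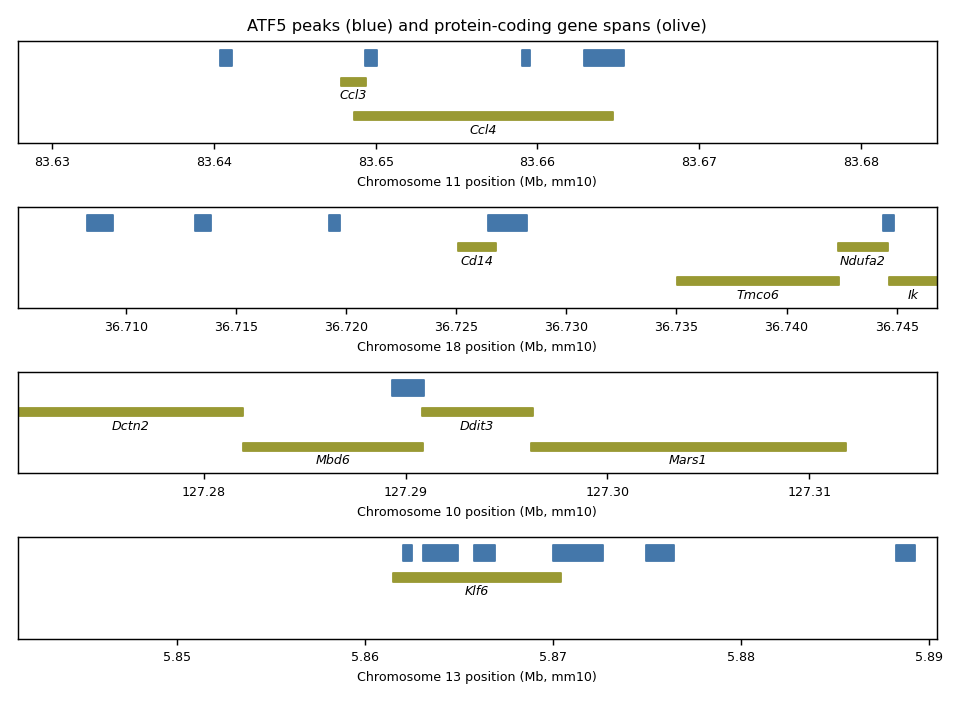
Maps of ATF5 peaks (blue) and protein-coding gene spans (olive) along the chromosome (x axis, Mb, mm10) at Ccl3 and Ccl4, Cd14, Ddit3 and Klf6, each with 20 kb to either side. The panels show 4, 5, 1 and 6 peaks in this order, and the Ddit3 peak covers the junction with Mbd6.

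Genes of the mitochondrial unfolded protein response and protein quality control were examined first, as ATF5 is known for its part in that response. A boundary peak was present at 5 of 22 members (22.7%, exact 95% interval 7.82 to 45.4), 2.91 times the mean of matched random lists, and 262 of 10000 random lists held as many or more, which missed the threshold of 250. The members were Hspa9, the mitochondrial HSP70 chaperone (921 bp, chromosome 18, 34954279 to 34955199), Dnaja3, its mitochondrial co-chaperone (628 bp), the inner-membrane proteases Yme1l1 (638 bp) and Afg3l2 (500 bp), and Atf5 itself. The Atf5 peak (500 bp, chromosome 7, 44815751 to 44816250) lay inside the gene, 658 bp from its higher end. No boundary peak was listed at Hspd1 and Hspe1, which encode the mitochondrial chaperonin and its partner, or at the matrix protease genes Lonp1 and Clpp, where the nearest peaks were 54.2, 64.6, 90.0 and 14.7 kb away. The list passed the threshold with a window of 500 bp (99 random lists), with one of 2500 bp (220), with unmatched random lists (152) and with each peak counted once (226, chosen after seeing the data). It did not pass it with peaks longer than 500 bp (3 of 22 members, 350 random lists) or without chromosomes X and Y (267, also chosen after seeing the data). The 5 members had 5 distinct peaks, so counting each peak once left the observed count unchanged. Counts of random lists this near 250 also vary from draw to draw, and that variation was not measured. With peaks anywhere in the gene or within 10000 bp of it, 7 of 22 members had a peak (31.8%) and 2067 random lists held as many or more.

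The integrated stress response list, genes activated when translation is held back under stress, did not stand apart from random lists. Of its 32 members, 3 had a boundary peak (9.38%, 1.98 to 25.02), and 3605 of 10000 random lists held as many or more. These were Ddit3, Herpud1, a gene of endoplasmic reticulum quality control (633 bp), and Atf5. At Atf4, which encodes the central activator of this response, the nearest peak was 171 kb away. Within the gene and 10000 bp around it, 5 of 32 members had a peak (15.6%), and 7484 random lists held as many or more.

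Inflammatory genes of the LPS response carried boundary peaks more often than matched random lists. A peak was present at 11 of 30 members (36.7%, 19.9 to 56.1) against a random mean of 5.62%, a 6.52-fold difference, and 0 of 10000 random lists held as many. Besides Ccl4 and Acod1, they included the chemokine gene Ccl3 (775 bp) and Cd40, a co-stimulatory receptor gene (773 bp). The tumour necrosis factor gene Tnf had a peak of 500 bp that began 697 bp from the gene (chromosome 17, 35198170 to 35198669). The other members with a peak were Tnfaip2, Tnfaip3, Cxcl2, Cxcl3, Cd83 and Zfp36, which are named here because their list was called. The annotated span of Ccl4 overlaps the end of Ccl3, so the Ccl3 peak also lay at the lower boundary of Ccl4. Il1b, the interleukin-1β gene, had no boundary peak, and its nearest peak was 1.89 kb away. Within the gene and 10000 bp around it, 22 of 30 members had a peak (73.3%, 54.1 to 87.7), and 0 of 10000 random lists held as many. In this wider count a single peak can count for neighbouring members, as between Ccl2 and Ccl7. Counting each peak once was run for boundary peaks only. Among peaks longer than 500 bp, 5 of 30 members had one (16.7%), and 11 random lists held as many or more.

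Genes of Toll-like receptor signalling and antimicrobial defence stood apart from random lists when peaks in the gene or within 10000 bp of it were counted, but not within 1000 bp of their boundaries. Over all protein-coding genes the wider count was 4708 of 21774 (21.6%). Of 30 members of the Toll-like receptor list, 4 had a boundary peak (13.3%, 3.76 to 30.7; 1667 random lists held as many or more). These were Cd14, the LPS receptor gene Tlr4 (652 bp), the NF-κB subunit gene Relb (636 bp) and the adaptor gene Myd88 (500 bp). The list passed the threshold with a window of 2500 bp, where 9 of 30 members had a boundary peak (30.0%, 14.7 to 49.4; 26 random lists). With a peak in the gene or within 10000 bp of it the count was 17 of 30 (56.7%, 37.4 to 74.5), and 0 random lists held as many. Of 27 antimicrobial effectors, 2 had a boundary peak (7.41%, 0.910 to 24.3; 4796 random lists), which were Acod1 and the lysozyme gene Lyz1 (652 bp), while 13 had a peak in the gene or within 10000 bp (48.1%, 28.7 to 68.1; 0 random lists). The Lyz1 peak also counted for its neighbour Lyz2 in this wider count. Among the interferon-response genes, 5 of 26 had a boundary peak (19.2%, 6.55 to 39.4), and 330 random lists held as many or more. These were Oasl2 (888 bp), Cxcl10 (698 bp), Gbp5 (661 bp), Irf9 (638 bp) and Gbp2 (500 bp). The interferon list passed the threshold with peaks longer than 500 bp (59 random lists) and with a window of 500 bp (185), but not with a peak in the gene or within 10000 bp (8 of 26, 30.8%, 932 random lists).

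Genes of autophagy and the lysosome carried boundary peaks at 7 of 27 members (25.9%, 11.1 to 46.3), against a random mean of 7.45%, and 30 of 10000 random lists held as many or more. They included Gabarap, an autophagosome membrane protein gene (795 bp), Becn1 and Uvrag, which encode parts of the lipid kinase complex of autophagy (685 and 655 bp), and the lysosomal sialidase gene Neu1 (638 bp). Within the gene and 10000 bp around it, 19 of 27 members had a peak (70.4%, 49.8 to 86.2; 0 random lists held as many). Genes of mitochondrial dynamics and mitophagy did not stand apart: 2 of 26 had a boundary peak (7.69%, 0.946 to 25.1; 5341 random lists), the fission adaptor gene Fis1 and the autophagy receptor gene Sqstm1, each of 500 bp. Dnm1l, which encodes DRP1, had 1 peak within its span or 10000 bp of it and none at a boundary. With the wider definition 6 of 26 members had a peak (23.1%; 5228 random lists). Subunit genes of oxidative phosphorylation had boundary peaks at 3 of 27 members (11.1%, 2.35 to 29.2; 3412 random lists), Atp5b, Ndufb5 and Sdhd, each of 500 bp, and peaks by the wider definition at 8 of 27 (29.6%; 1011 random lists).

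Genes of bZIP transcription factors, the family of ATF5, had boundary peaks at 10 of 41 members (24.4%, 12.4 to 40.3) against a random mean of 6.25%, and 0 of 10000 random lists held as many. The longest were at Ddit3, Nfe2l2, the gene of the oxidative stress regulator NRF2 (1174 bp), the AP-1 gene Junb (892 bp) and Atf6, an activator of the endoplasmic reticulum stress response (820 bp). By the wider definition 19 of 41 members had a peak (46.3%; 2 random lists). Ribosomal protein genes, which are active in nearly every cell, also passed the threshold, with 6 of 30 members (20.0%, 7.71 to 38.6; 50 random lists held as many or more), among them Rps9 (803 bp), Rpl3 (647 bp), Rpl14 (642 bp) and Rps23 (500 bp). By the wider definition the count was 9 of 30 (30.0%; 77 random lists). Macrophage identity genes had boundary peaks at 2 of 27 members (7.41%; 5062 random lists), the scavenger receptor gene Cd68 (625 bp) and the integrin gene Itgam (500 bp). By the wider definition 12 of 27 had a peak (44.4%, 25.5 to 64.7; 57 random lists), including Spi1, the gene of the myeloid regulator PU.1, with 2 peaks.

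Few marker genes of other cell types had a boundary peak. None was listed at 25 neuron markers, 25 hepatocyte markers or 25 stromal fibroblast markers (each 0%, exact upper 95% bound 13.7%) or at 20 neutrophil markers (0%, upper bound 16.8%), and 1 of 25 lymphocyte markers had a peak (4.00%, 0.101 to 20.4). Counts as low or lower occurred in 1968, 1913, 2293, 2948 and 4855 of 10000 random lists in this order. With boundary peaks, lists of this size could not have passed the threshold on the lower side even with a count of 0. These counts therefore do not show whether peaks at such genes were rarer than at other genes. By the wider definition the counts were 5 of 25 for neurons, 1 of 25 for hepatocytes, 3 of 25 for stromal cells, 5 of 20 for neutrophils and 4 of 25 for lymphocytes. Counts as low or lower then occurred in 1803, 350, 1353, 9461 and 4032 of 10000 random lists in this order, so none passed the threshold on the lower side. For neutrophils, 1510 random lists held as many or more. At the liver gene Alb the nearest peak was 135 kb away. Of the 5 neutrophil markers with a peak by the wider definition, S100a8, S100a9, Ltf and Lcn2 are also on the antimicrobial list, and were named after their values were seen.

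**Figure D4:**
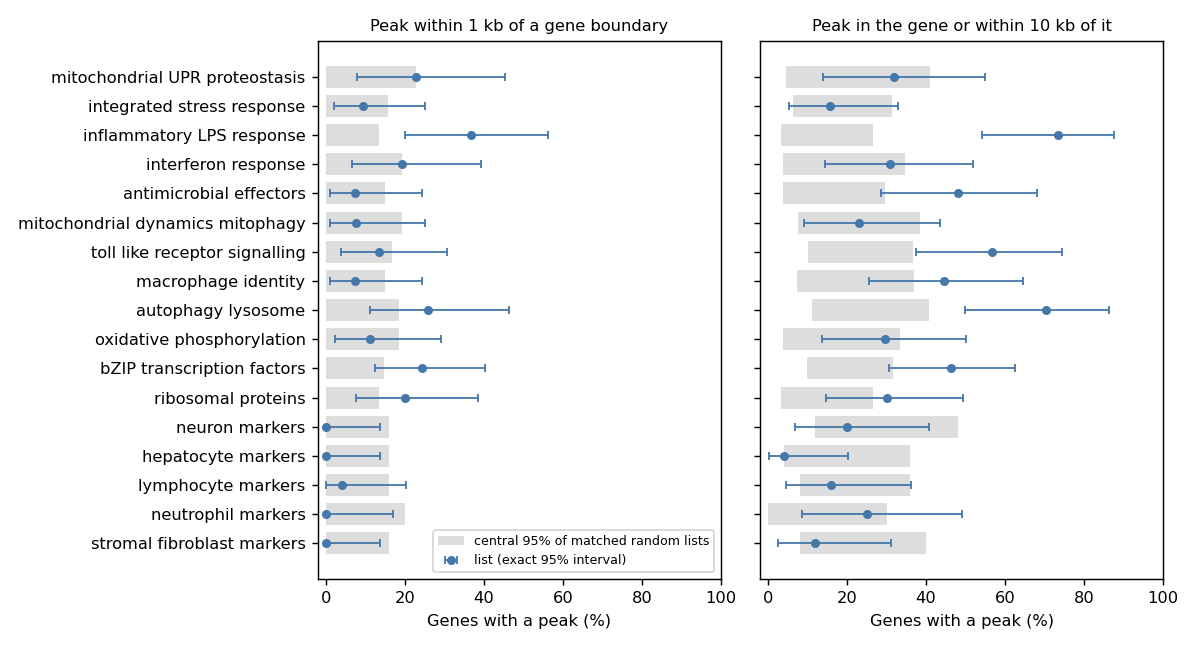
Points show the percentage of each list's genes (x axis) with an ATF5 peak within 1000 bp of a gene boundary (left) or in the gene or within 10 kb of it (right), with exact 95% intervals, and grey bars show the central 95% of 10000 matched random lists. Inflammatory genes lie at 36.7% on the left and 73.3% on the right, beyond the grey bars, while the neuron, hepatocyte, neutrophil and stromal lists lie at 0% on the left.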

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

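Signal outside the analysed chromosomes was found in 6 peaks on contigs of chromosome 4, on which no gene was compared. Of these, 5 lay on the contig 4_GL456216_random, between positions 9204 and 29193, with lengths from 500 to 820 bp, and 1 lay on 4_JH584292_random (8194 to 8693, 500 bp). They entered no comparison because no annotated gene was compared on these contigs. The list gives no control value for any region, and no explanation was tested.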

How the results depend on the processing

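The excess of peaks at gene boundaries, the low density on chromosome X and the calls of the inflammatory, autophagy and lysosome, bZIP and ribosomal protein lists kept their direction and side of the threshold under each alternative run for them. Some lists that were not called crossed their random mean. The integrated stress response list went from 1.41 to 0.830 times it by the widest definition. With a window of 500 bp the antimicrobial list went from 1.25 to 0.763 times it, and the macrophage list from 1.19 to 0.719. Among peaks longer than 500 bp, 0 members of the oxidative phosphorylation and mitochondrial dynamics lists had a boundary peak. The share in gene bodies, above the random maximum as reported, fell within the random range with peaks longer than 500 bp, a window of 2500 bp and all annotated genes; the cause was not tested. With peaks longer than 500 bp the list held 2365 peaks over 1.85 Mb, the X ratio was 0.0917 (chosen after seeing the data), 18.2% of peaks lay at a boundary (5.75-fold over random) and 40.1% in the class other, and 583 genes had a boundary peak. A window of 500 bp gave 10.8% at boundaries (6.62-fold), 44.0% in bodies and 45.1% other. A window of 2500 bp gave 21.5% (2.99-fold), 37.8% and 40.7%. All annotated genes gave 18.5% (2.90-fold), 47.1% and 34.4%, and any overlap gave 16.0% at boundaries (4.04-fold). The wider the boundary class is drawn, the more peaks it takes by construction. The mitochondrial unfolded protein response list, just outside the threshold with 262 random lists, passed it with a window of 500 bp (99), a window of 2500 bp (220), unmatched random lists (152) and each peak counted once (226, chosen after seeing the data), but not with peaks longer than 500 bp (350), the widest definition (2067) or without chromosomes X and Y (267), and its call is therefore undecided; the cause was not tested. Of the lists not called, the interferon list passed under 2 alternatives, the Toll-like receptor list under 2 and the antimicrobial and macrophage lists under the widest definition alone. Leaving out chromosomes X and Y, also chosen after seeing the data, changed no call. The repeat filter and every motif, GC content and peak score alternative were not run, as sequence and scores were not used here. The depth of the libraries is unknown, and with 1 library per antibody leaving out a replicate was not possible. No paired analysis was possible because no antibody has a replicate.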

Other observations

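The replication-dependent histone genes, the symbol families, the tRNA genes and the runs of neighbouring peaks described here were chosen after seeing the data, as were the tests of X copy number, of active promoters (both) and of tRNA clusters on chromosome 13. Peaks gathered in runs at several genes. With gaps of at most 12.5 kb, 17 runs of 5 or more peaks held 95 peaks, while 100 random placements gave at most 1 such run. They included runs at Cd36, the gene of a scavenger receptor for lipids (7 peaks, chromosome 5, 17834487 to 17857586), at Psap, which encodes the precursor of the lysosomal saposins (6 peaks), at Klf6 and at Lcp1, the gene of the leukocyte actin-bundling protein L-plastin (6 each). Runs of 5 lay at Tnfaip3, an inhibitor of NF-κB signalling, at Cd14, at Ell2 and at the receptor genes Tnfrsf1b and Tnfrsf8. The other runs of 6 lay at Zfp91 and Lpxn, at Zfp217 and at Mid1, and the other runs of 5 at Abt1 and Btn1a1, at Bmt2, and at 3 places with no protein-coding gene within 10 kb, on chromosomes 10, 16 and Y. Of all peaks, 25.2% had a neighbour within 12.5 kb, against a random maximum of 9.42%. Of the 2507 peaks far from genes, 17.8% did, against a random maximum of 7.10%. When all peaks of the list closer than 2500 bp were merged, 19.7% of the resulting 7261 peaks did, against a random maximum of 8.84%.

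The other run of 7 peaks (chromosome 13, 23518666 to 23556560) lay among histone genes from H4c8 to H3c6. Replication-dependent histone genes, which are expressed during DNA synthesis, had a boundary peak at 26 of 63 members (41.3%, exact 95% interval 29.0 to 54.4) through 17 distinct peaks, against a random mean of 6.41%. This group was looked at because of the run, so its count is no independent evidence. Without the genes at the run and with each peak counted once, 55 members held 13 distinct peaks, against a mean of 3.51 and a maximum of 11 over 10000 random lists. Neighbouring histone genes share clusters, which the random lists do not copy. Among 111 families of at least 20 genes sharing a symbol stem, 10 were called higher, where chance gives 1.65, and 3 were called lower, where chance gives 0.268. The count of 0 lies past the threshold in 21 of the families, and the others could not have been called lower. The higher ones included the stems of cytosolic ribosomal proteins (Rps 9 of 44, Rpl 9 of 53), mitochondrial ribosomal proteins of the large subunit (Mrpl, 10 of 49, 20.4%), the vesicle GTPases (Rab, 13 of 69) and the C-type lectins (Clec, 7 of 33). A stem can also take in genes of other kinds whose symbols begin alike, so these are not counts of the named proteins alone. The lower ones were olfactory receptors (Olfr, 12 of 1109, 1.08% against a random mean of 5.31%), vomeronasal receptors (Vmn, 4 of 352) and keratins (Krt, 0 of 53).

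Genes for tRNA had a peak far more often than random placements gave: 97 of 403 (24.1%, Wilson 95% interval 20.2 to 28.5), against a random mean of 0.848% and a maximum of 3.23%, through 53 distinct peaks. Clusters of tRNA genes on chromosome 13 were argued against as the whole cause, since 18.79% of 149 tRNA loci on other chromosomes, with genes within 10000 bp joined, had a peak (13.3 to 25.8; random maximum 4.03%). Neighbouring protein-coding boundaries were also argued against as the whole cause, though narrowly. Of 89 loci more than 10000 bp from any such boundary, 12.36% had a peak (7.04 to 20.8), and the lower bound was just above the random maximum of 6.74%. This margin rests on the highest of 1000 placements, and the test was undecided before the genes on scaffolds were left out. Over all 174 loci the share was higher, at 21.8% (16.3 to 28.5), so a part played by these boundaries stays open. No biological explanation was tested, and binding of ATF5 at tRNA genes stays open.

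Chromosome X held fewer peaks per Mb than every autosome. A lower number of protein-coding genes was argued against as the whole cause, since the share of genes with a boundary peak was also lower on X, at 11 of 963 (1.14%) against 1430 of 20558 on the autosomes (6.96%), a ratio of 0.1642 (95% interval 0.0911 to 0.296). The ratio of peaks per Mb, 0.1376, fell to 0.126 (0.0990 to 0.161) without the run of 6 peaks at Mid1, near the end of the chromosome. Whether that run lies in sequence that X shares with another chromosome was not examined. A single copy of X per cell may lower read heights and push peaks under the caller's threshold, and cannot be told apart from other explanations, because the list gives no heights and the labels give no sex. Peaks longer than 500 bp made up 20.8% (13.1 to 31.6) of those on X and 31.3% (30.2 to 32.3) of those on autosomes.

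For the excess of boundary peaks at inflammatory genes, the explanation of one peak counted for several neighbouring genes was argued against: with each peak counted once, 0 of 10000 random lists reached the 11 distinct peaks. Another explanation was that any active promoter of the macrophage gave a peak. Of 57 ribosomal protein and oxidative phosphorylation genes, active in nearly every cell, 15.79% had a boundary peak (exact 95% interval 7.48 to 27.9), where most would need one. The share shows only that most of these 57 genes had no listed boundary peak. A boundary peak was listed at 6.62% of all protein-coding genes, and the caller's threshold is unknown. Active promoters with signal below that threshold would give no peak, so the share cannot decide on that explanation. The bar was also set after the share had been seen. Macrophage identity genes were at 7.41% against a random mean of 6.24%, but at 44.4% by the wider definition. Starts and ends of genes were not separated, so promoters were not examined as such. That active promoters gave peaks more often than other genes cannot be told apart from binding favoured at certain groups of genes. The ribosomal list passed the threshold (50 of 10000 held as many or more), the oxidative phosphorylation list did not (3412), and activity was not measured here. The bZIP list (10 of 41 members, 0 random lists) and the autophagy and lysosome list (7 of 27, 30 random lists) were also called. The excess was therefore not confined to inflammatory genes. The design names no unstimulated macrophages, so whether these peaks follow LPS was not tested.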
